A study of Mus musculus with 8 samples.

How the data were processed

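RNA from the left ventricle of 8 male mice aged 8 weeks was measured on 8 arrays, 1 per mouse, with 4 wild type mice and 4 mice that overexpressed the microRNA miR-100 in the heart. The labels give the strain as C57/BL6J and describe all mice as untreated. Litters and collection times were not given in the sources used here. The arrays are read as separate mice from the study's design, and p-values measure only the spread between these 8 samples.

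Per the labels' protocols, total RNA was extracted with TriPure, amplified and converted to fragmented cDNA with the Affymetrix WT Plus kit, and labelled with biotin. The deposited values are log2 signals per transcript cluster, which is a group of probes designed against a single transcribed region. They were made by the authors with Transcriptome Analysis Console 4.0, per the submitters' processing notes. The summarization, the normalization method and the genome build were not given in the sources used here. The deposited columns had medians between 5.70 and 5.74, so the arrays had been brought to a common scale before deposit. Values carried 2 decimals and ran from 2.29 to 19.93. The upper end was shared by 9 rows on 1 or more arrays, which marks a ceiling, and differences between samples are compressed near it. Signal and not read depth limits precision on an array, and dim rows lie close to the array's background.

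The table held 22206 rows. The platform annotation supplied with the series gave 1 gene symbol for 19572 rows, several symbols for 0 rows and none for 2634 rows, which are unnamed here. All 19572 Entrez numbers were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through it. That table was used for names, synonyms and gene order, and no coordinates are reported. Where several rows carried a symbol, which held for 55 symbols, the row with the highest mean over the 8 arrays stood for the gene in the lists. All 260 rows that shared every value with another row were kept.

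No values were transformed or filtered before the main test. Group differences were fitted with limma 3.58.1 in R 4.3.3, by linear models and empirical Bayes moderation without covariates, and p-values were adjusted by Benjamini-Hochberg over all 22206 rows with a threshold of 0.05. Differences are miR-100 overexpressing minus wild type on the log2 scale, given with the moderated standard error (SE), and 95% confidence intervals come from the same fit. Group means are given with the standard deviation (SD). The levels of Nox4 and Cd36 were compared with a two-sided exact permutation test over all 70 assignments, whose smallest possible p is 0.0286. Shifts of 39 gene lists with 5 or more measured members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists. In addition, members of each list were adjusted over the list alone.

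The groups, the tests, the 41 gene lists, the alternatives and the rule for naming genes were set before the data were examined. By that rule the text names, among rows with 1 symbol that were not predicted loci, passed the threshold and had no overlap between groups, the 12 with the largest rise and the 12 with the largest fall. Where fewer than 12 passed in a direction, all that passed are named, filled up to 6 if needed. The rule also names Nox4, Cd36, any row for the miR-100 host locus, and from each list the members past the threshold with the largest rise and fall, up to 2 each, or the member with the lowest unadjusted p for the lists that are described. Other list members, and the remaining genes past the threshold, are named after their values were seen.

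The tests were run first on simulated data. In 10 simulations of this comparison with the real row means and residual spreads, 22206 rows and 200 changed rows each, limma recovered 5.08% of rows changed by 0.5 on the log2 scale, 63.6% of those changed by 1 and 97.4% of those changed by 2, and 4.18% of the calls were false. A list shifted by 0.2 was found in 10 of 10 simulations, and 1 list call in all was made with nothing changed. The rows were simulated independently of each other, so these list results do not cover lists whose genes are correlated.

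The alternatives were an intensity trend or robust moderation, array weights, quantile normalization, median centring, filters at the 25th and 50th percentile of row means, rows with a symbol alone, other thresholds, a block for the replicate number, camera with an estimated correlation, limma's fry, and leaving out each array in turn. The search for miR-100 seed sites in 3 prime UTRs was not run, since it needs transcript sequences that were not used here. No row carried the name of Mir100, its host gene Mir100hg or the clustered Mirlet7a-2 and Mir125b-1, with 0 rows each, so the overexpression itself was not checked here.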

Results

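Left ventricular heart muscle of 8 male mice was profiled on expression arrays, with 4 wild type mice and 4 mice overexpressing miR-100 in the heart. MicroRNAs such as miR-100 pair with messenger RNAs and lower their stability or translation, and the comparison asks which transcripts differ in the untreated heart when this microRNA is raised. The arrays resembled each other closely, with correlations between 0.988 and 0.993 over all rows. The first principal component held 21.7% of the variance and the second 16.6%. Wild type replicate 2 lay apart from the other arrays, with a first component score of -38.2 against -13.0 to -3.49 in the other wild type arrays and 8.96 to 30.8 in the miR-100 arrays. The median difference over all rows was -0.015 on the log2 scale, and the number of arrays limits the precision of every value. No row carried the name of miR-100 or its host gene, so its own level is not given.

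Overexpression of miR-100 went with higher expression of a small set of genes and lower expression of a smaller set. Cd59a, which encodes a membrane-anchored inhibitor of the complement attack complex, rose 7.07-fold, from 11.19 ± 0.20 to 14.02 ± 0.46 (log2 signal, mean ± SD, n = 4 each). Ndnf, a secreted neurotrophic factor, rose 6.73-fold, and Lcn2, a secreted iron-siderophore binding protein of innate immunity, rose 6.79-fold. Alox5, the lipoxygenase that starts leukotriene synthesis, fell by 1.99 on the log2 scale, from 7.69 ± 0.41 to 5.71 ± 0.34 (SD, n = 4 each). Nfkbia, which encodes the inhibitor of NF-kappaB, fell by 1.15, and Wee1, a kinase that restrains entry into mitosis, fell by 1.33.

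In all, 31 of 22206 rows passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), of which 21 were higher and 10 lower in the miR-100 hearts. The 28 rows with a gene symbol comprised 20 higher and 8 lower. In each of the 31 rows the 4 values of the groups did not overlap. Across all rows 4.54% had no overlap, against the 2.86% that chance gives. At an unadjusted p under 0.05 there were 1716 rows, 7.73% of the table, with 789 higher and 927 lower.

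Among the higher genes, the log2 difference was 2.82 for Cd59a (SE 0.21, adjusted p = 0.000108, limma) and 2.75 for Ndnf (SE 0.22, adjusted p = 0.000108, limma). Cd59b, a neighbouring related copy of Cd59a whose probes may not tell both transcripts apart, had a difference of 2.14 (SE 0.29) and is uncertain for that reason. Lcn2 differed by 2.76 (SE 0.48, adjusted p = 0.0431, limma) with a wide spread among the wild type samples (SD 1.12). Ptgds, a prostaglandin D synthase, reached 16.35 ± 0.50 against 14.36 ± 0.76 in wild type hearts (SD, n = 4 each), a difference of 1.99. The endocytic adaptor gene Epn3 rose by 1.64 and the O-glycan branching enzyme Gcnt1 by 1.60. Pygl, the liver form of glycogen phosphorylase, rose by 1.56, and the neutral amino acid transporter Slc38a1 by 1.31. The pacemaker channel gene Hcn2, Jpt1 and the stress granule protein gene G3bp2 rose by 1.24, 1.18 and 1.13. The remaining 8 named rows that rose were Klhdc8a, Cnksr3, Ankrd23, Hk1, Pyroxd2, Sulf2, Prdm1 and Fig4, and the smallest rise was 0.91.

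Among the lower genes, Alox5 had a log2 difference of -1.99 (SE 0.22, adjusted p = 0.00248, limma). Armc2 followed with -1.37 (SE 0.24) and Wee1 with -1.33 (SE 0.18, adjusted p = 0.0140, limma). A row of the nuclear receptor gene Rora differed by -1.26 (SE 0.22), whereas its other rows had differences of -0.28 and -0.08 that did not pass, so the rows of this gene disagree. Nfkbia differed by -1.15 (SE 0.18, adjusted p = 0.0252, limma). The calcium sensor gene Hpcal1 fell by 1.10, the muscle fructose bisphosphatase gene Fbp2 by 1.07, and Mid1ip1, a regulator of acetyl-CoA carboxylase, by 1.01.

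**Figure D1:**
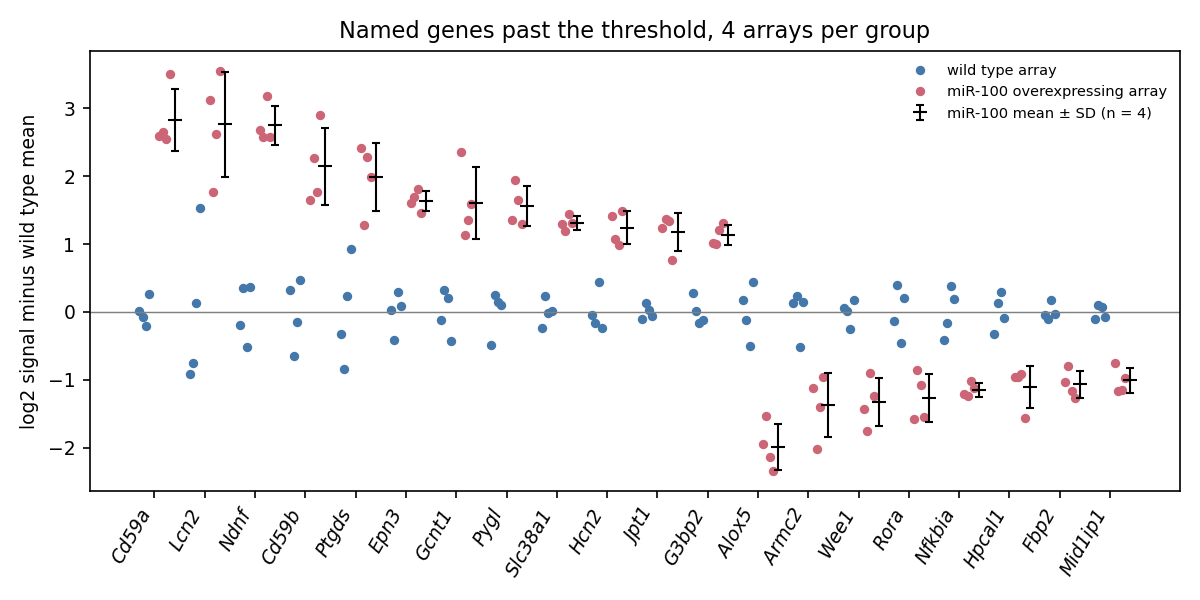
Log2 signal minus the wild type mean (vertical axis) for the named genes past the threshold (horizontal axis), with a point for each of the 4 wild type and 4 miR-100 overexpressing arrays and the mean ± SD of the miR-100 group. The groups do not overlap in any of these genes, and the miR-100 means run from 2.82 for Cd59a to -1.99 for Alox5.

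Of the 31 rows, 8 passed in each of the 8 fits that left out an array, namely Alox5, Cd59a, Cd59b, Epn3, Ndnf, Pygl, Slc38a1 and an unnamed row, while Prdm1 passed in 0 of them. All 31 kept their direction, which had to follow since their groups did not overlap. The count of rows fell to 15 without wild type replicate 2 or 3, to 12 without miR-100 overexpressing replicate 1, and to 11 without replicate 3 or 4 of that group. Of the 31 rows, 18, 12, 14 and 20 still passed without wild type replicates 1 to 4 in turn, and 11, 21, 11 and 10 without the miR-100 overexpressing replicates 1 to 4. With quantile normalization Lcn2, Armc2 and Hpcal1 had limma adjusted p of 0.0534, 0.0513 and 0.0546 and no longer passed.

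Nox4, an NADPH oxidase that produces hydrogen peroxide, and Cd36, a fatty acid transporter, are genes that cardiac miR-100 work has followed as candidate targets, and neither passed a test here. Nox4 had 4.62 ± 0.26 in wild type and 4.39 ± 0.16 in miR-100 hearts (log2 signal, SD, n = 4 each), a difference of -0.23 (95% confidence interval -0.58 to 0.13, two-sided exact permutation p = 0.229, limma adjusted p = 0.818). Its mean stood at percentile 32.4 of all row means, so the gene was dim on this array. Without wild type replicate 3 the difference was -0.30 with an exact permutation p of 0.0286, and this was the 1 fit of the 8 without an array that passed. Cd36 had 17.58 ± 0.14 and 17.52 ± 0.05 (SD, n = 4 each), a difference of -0.06 (95% confidence interval -0.36 to 0.23, two-sided exact permutation p = 0.543, limma adjusted p = 0.956). It stood at percentile 99.6 of all row means. These genes may have been chosen on these samples, so their direction is not independent evidence, and 0 of the 2 passed either over all genes or adjusted over the list alone.

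Of 29 measured genes reported or predicted as targets of the miR-99/100 family, 0 passed over all genes and 0 passed adjusted over the list alone. Of these, 20 had differences below 0, the median was -0.10, and camera gave an adjusted p of 0.417. In the simulations limma recovered 5.08% of rows changed by 0.5, so the count of 0 does not show that the targets were unaffected. The arrays measure RNA, so an effect on translation alone would not be seen. The chromatin remodelling gene Smarca5 had the lowest unadjusted p of the list, at 11.03 ± 0.18 against 10.61 ± 0.15 (SD, n = 4 each), a difference of -0.42 (limma adjusted p = 0.459). Mtor differed by -0.20 and the receptor gene Igf1r by 0.17, and neither passed. Without single arrays Mtor ran from -0.40 (without miR-100 overexpressing replicate 2) to -0.11 (without wild type replicate 3) and Igf1r from 0.09 (without wild type replicate 3) to 0.24 (without wild type replicate 4).

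In energy metabolism, camera called the list of glucose uptake and glycolysis higher (adjusted p = 0.0321) and that of fatty acid oxidation lower (adjusted p = 0.00906), with adjusted p = 0.604 with an estimated correlation for both. Hk1, the hexokinase that phosphorylates glucose on entry, rose from 13.17 ± 0.29 to 14.25 ± 0.22 (log2 signal, SD, n = 4 each), and Pgam1, a phosphoglycerate mutase, rose by 0.58 when adjusted over the list alone. Of 23 glycolysis genes 18 had differences above 0, 1 passed over all genes and 2 passed adjusted over the list alone. The list's median difference was 0.09. Hk1 passed over all genes in 2 of the 8 fits without an array (highest limma adjusted p = 0.132), and 1 member passed adjusted over the list alone without wild type replicate 2 or 3 or miR-100 overexpressing replicate 1, 3 or 4. The camera call was lost without wild type replicate 1 (0.0903) or 4 (0.102) and without miR-100 overexpressing replicate 1 (0.0560), 2 (0.0678), 3 (0.0941) or 4 (0.0559), and with quantile normalization (0.0779).

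Of 27 fatty acid oxidation genes, 23 had differences below 0, and the median was -0.12. None passed over all genes (0 in limma, with 1716 rows of the table at an unadjusted p under 0.05), and 2 passed adjusted over the list alone, Acot1 at -1.02 (SE 0.25) and Acot2 at -0.59 (SE 0.16). Both encode thioesterases, which release fatty acids from coenzyme A and are not steps of beta-oxidation itself. Cpt1b, the muscle carnitine palmitoyltransferase that admits fatty acids to mitochondria, differed by 0.01 (SE 0.13). Adjusted over the list alone, 0 passed without wild type replicate 1 or 4 or miR-100 overexpressing replicate 1, 3 or 4, and 1 passed without wild type replicate 2 or 3. Without wild type replicate 1 the camera adjusted p was 0.0897, and without miR-100 overexpressing replicate 4 it was 0.120.

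Other metabolic lists did not shift by camera. Bdh1, the ketone body dehydrogenase, was the member of the pyruvate oxidation and tricarboxylic acid list (28 genes, camera adjusted p = 0.417) that rose when adjusted over the list alone, by 1.89 (SE 0.35), with an adjusted p of 0.0627 over all genes, and 0.0294 without miR-100 overexpressing replicate 1 (limma). That was 1 of the 8 fits without an array, among which its highest limma adjusted p was 0.187. Among 26 genes of fatty acid uptake and storage 0 passed either way, with 1 adjusted over the list alone without miR-100 overexpressing replicate 4, and camera gave 0.914. Among 43 subunits of oxidative phosphorylation 0 passed either way, with a median of -0.04 and a camera adjusted p of 0.703. Among 29 genes of mTOR, insulin and IGF signalling 0 passed either way (camera adjusted p = 0.552).

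Of 26 measured genes of the hypertrophic and fetal programme, 5 rose when adjusted over the list alone and 0 passed over all genes. Camera called the list higher, with an adjusted p of 0.0165, and adjusted p = 0.604 with an estimated correlation. The natriuretic peptide genes Nppa and Nppb, which the ventricle raises under load, had differences of 1.04 (SE 0.19) and 1.40 (SE 0.32). Ankrd1, a stretch-responsive cofactor of the sarcomere, differed by 1.10 (SE 0.22). Casq1, a skeletal muscle calsequestrin, differed by 0.89 and Rcan1, a calcineurin-responsive gene, by 0.58. Over all genes limma's adjusted p was 0.0616 for Nppa, and Ankrd1 passed (0.0427) without wild type replicate 4. That was 1 of the 8 fits without an array, and the highest limma adjusted p of Ankrd1 among them was 0.240. Myh7, the beta myosin heavy chain of the fetal heart, differed by -0.38 (SE 0.26) and did not pass, with -0.56 without miR-100 overexpressing replicate 1 and -0.18 without replicate 4 of that group. The list's median was 0.09, with 16 members above 0 and 10 below. The camera adjusted p was 0.108 without wild type replicate 2, 0.0560 without miR-100 overexpressing replicate 1 and 0.101 without replicate 2 of that group.

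Contractile genes showed few differences. In the sarcomere and costamere list of 29 genes, Dmd, which encodes dystrophin, fell when adjusted over the list alone, by 1.20 on the log2 scale (limma adjusted p = 0.0548 over all genes, 0.0484 with quantile normalization and 0.0343 without miR-100 overexpressing replicate 2). The last was 1 of the 8 fits without an array, among which the highest limma adjusted p of Dmd was 0.177. The heart muscle genes Tnnt2 and Myh6 differed by 0.02 and -0.04, with means of 19.80 and 19.15 that lie near the ceiling of 19.93. Atp2a2, the calcium pump of the sarcoplasmic reticulum, also lay near the ceiling at 19.85 and differed by -0.005. Among 26 ion channel and gap junction genes, Hcn2 passed over all genes, and 4 passed adjusted over the list alone. These were Hcn2 and the potassium channel gene Kcnq1, which rose by 1.24 and 0.61, and the sodium channel subunit gene Scn4b and the connexin gene Gjc1, which differed by -0.67 and -0.56. Adjusted over the list alone, 1 member passed without wild type replicate 3 or miR-100 overexpressing replicate 1 and 7 without miR-100 overexpressing replicate 4, and Hcn2 passed over all genes in 3 of the 8 fits without an array. The median of this list was -0.05, its mean 0.01, and camera gave an adjusted p of 0.912. Of 33 extracellular matrix and fibrosis genes 0 passed either way (camera adjusted p = 0.703), with 1 adjusted over the list alone without miR-100 overexpressing replicate 1 or 4.

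Clock genes differed in both directions. The activator genes Arntl and Clock were higher by 1.03 (SE 0.23) and 0.49 (SE 0.14), and the repressor genes Per1, Per2 and Per3 were lower, at -0.78, -0.89 and -0.81 (SE 0.18, 0.18 and 0.15). Dbp, an abundant output of the clock, went from 16.99 ± 0.23 to 16.33 ± 0.09 (log2 signal, SD, n = 4 each). Nr1d1, a repressor of Arntl, was higher by 0.80 (SE 0.19), while its relative Nr1d2 differed by 0.03 (SE 0.14). Of 18 measured members, 12 passed adjusted over the list alone, 4 of them higher, the fourth being Bhlhe40, and 8 lower, which also included Ciart, Cry2, Hlf and Tef. Without miR-100 overexpressing replicate 4 the count was 8, with 3 higher and 5 lower. None passed over all genes by the rows that stand for the genes (0 in limma, where Per3 had an adjusted p of 0.0548). A dimmer row of the list member Rora did pass, at -1.26 (limma adjusted p = 0.0421), while its other rows did not. Arntl (limma adjusted p = 0.0332) and Per2 (0.0387) passed without wild type replicate 1, in 1 of the 8 fits without an array. Their highest limma adjusted p in those fits were 0.381 and 0.296. The median difference was -0.32, and camera gave an adjusted p of 0.0247, with adjusted p = 0.604 with an estimated correlation. The camera value was 0.0897 without wild type replicate 1, 0.0751 without replicate 2 and 0.147 without replicate 4, and it was 0.0678 and 0.0559 without miR-100 overexpressing replicates 2 and 4.

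**Figure D2:**
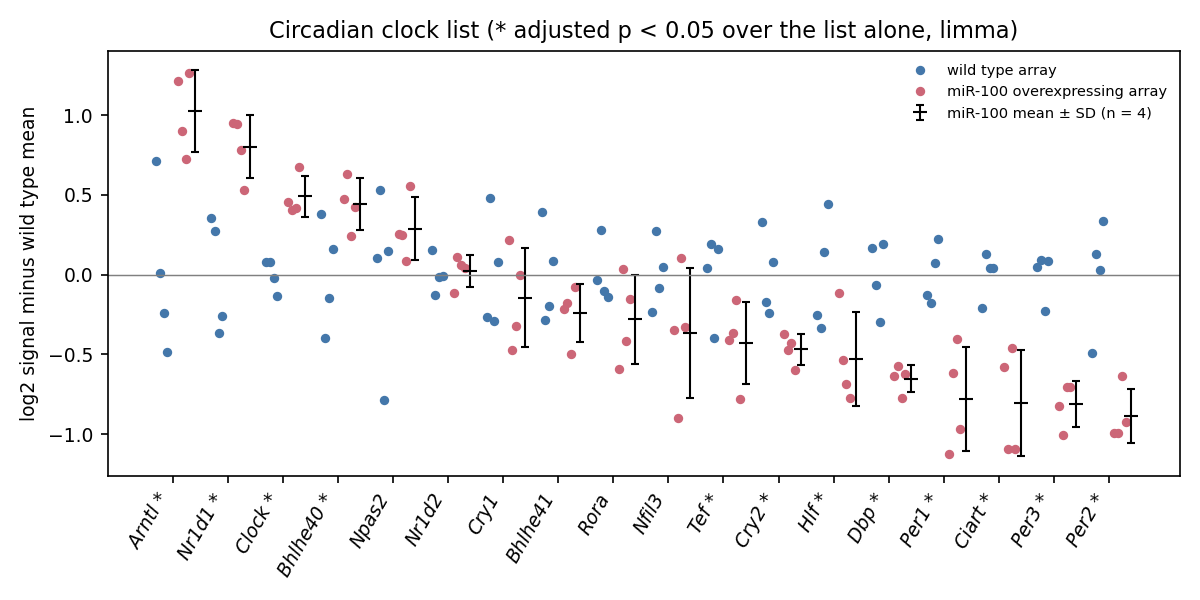
Log2 signal minus the wild type mean (vertical axis) for the 18 measured clock list genes (horizontal axis), with a point for each of the 4 wild type and 4 miR-100 overexpressing arrays and the mean ± SD of the miR-100 group. Stars mark the 12 genes past the threshold adjusted over the list alone, from Arntl at 1.03 to Per2 at -0.89.

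Of 28 interferon-induced genes 17 had differences above 0, and camera called the list higher with an adjusted p of 0.00906, and adjusted p = 0.802 with an estimated correlation. The median was 0.16, and 0 members passed over all genes or adjusted over the list alone in limma, while 9 were higher at an unadjusted p under 0.05. Adjusted over the list alone, 5 were higher without wild type replicate 3 and 2 without wild type replicate 2. Ifit2, with the lowest unadjusted p of the list, had 6.99 ± 0.28 in wild type and 7.60 ± 0.30 in miR-100 hearts (SD, n = 4 each), and Ifit1, Ifit3 and Mx2 differed by 0.67, 0.64 and 0.62. The immunoproteasome gene Psmb9 differed by -0.46. The camera adjusted p was 0.184 without wild type replicate 4, 0.122 without miR-100 overexpressing replicate 2 and 0.0527 without replicate 4 of that group, and 0.111 among the brighter rows alone. Markers of macrophages, cells that also express interferon-induced genes, had a median difference of -0.12 over 17 genes (camera adjusted p = 0.249).

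Among 33 genes of inflammatory cytokines, chemokines and receptors, Lcn2 and Nfkbia passed over all genes, and 4 passed adjusted over the list alone. The others were the lipopolysaccharide receptor gene Tlr4, higher by 0.68, and the chemokine gene Ccl9, at -0.96. Without wild type replicate 1 or miR-100 overexpressing replicate 2 or 3, 2 passed adjusted over the list alone, and over all genes Lcn2 passed in 2 and Nfkbia in 1 of the 8 fits without an array. The median was -0.03, the mean 0.03 and the camera adjusted p 0.918. In antioxidant defence 4 of 36 genes rose when adjusted over the list alone and 0 passed over all genes. These were Txnip, which binds and inhibits thioredoxin, by 1.28, the glutathione peroxidase gene Gpx1 by 0.77, the glutathione transferase gene Gstm2 by 0.73 and the extracellular superoxide dismutase gene Sod3 by 0.72, and camera gave 0.251. Without wild type replicate 2 Txnip passed over all genes (limma adjusted p = 0.0411). That was 1 of the 8 fits without an array, among which the highest limma adjusted p of Txnip was 0.180. Of 17 genes for NADPH oxidases and other oxidant producers 0 passed either way (camera adjusted p = 0.757). In the p53 and cell death list, 4 of 21 genes rose when adjusted over the list alone and 0 passed over all genes, with a median of -0.005, a mean of 0.17 and a camera adjusted p of 0.249. They were the cell cycle inhibitor Cdkn1a (2.06, SE 0.53), Phlda3 (1.10), Eda2r (0.88) and the cell death inhibitor Bcl2 (0.62). Phlda3 was dim, at percentile 32.1 of all row means, which limits how exactly its difference is known.

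In the heat shock list of 15 genes, the chaperone gene Hsp90aa1 rose by 0.83 when adjusted over the list alone, and camera gave 0.757. That count was 0 without miR-100 overexpressing replicate 1, 2 or 3 and 2 without replicate 4. Of 27 immediate early genes 0 passed either way, the median was -0.11 and camera gave 0.176, with 1 lower adjusted over the list alone without wild type replicate 1 or 3. Egr1, the member with the lowest unadjusted p, had 8.93 ± 0.98 in wild type and 7.66 ± 0.32 in miR-100 hearts (SD, n = 4 each). Over all genes it passed in 1 of the 8 fits without an array, that without wild type replicate 3 (limma adjusted p = 0.0240). Its highest limma adjusted p in those fits was 0.549. The 7 lists for mitochondrial biogenesis, calcium handling, autophagy, the unfolded protein response, hypoxia, the cell cycle and cytosolic ribosomal proteins had 0 members past the threshold over all genes or adjusted over the list alone, and their lowest camera adjusted p was 0.207, for calcium handling. The mixed fry test, which asks whether members change in either direction, called calcium handling (adjusted p = 0.00310) and hypoxia (adjusted p = 0.0140) among them. Adjusted over the list alone, 2 hypoxia genes passed without wild type replicate 2 and 1 cell cycle gene without wild type replicate 3.

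No marker list of another cell type passed camera. Across 13 marker lists the medians ran from -0.12 in macrophages to 0.005 in neutrophils, and the lowest camera adjusted p was 0.249. The mixed fry test called the markers of atrial and conduction tissue (adjusted p = 0.000114) and of pericytes and smooth muscle (adjusted p = 0.00448). In 4 of the lists a single member passed adjusted over the list alone. These were the smooth muscle actin gene Acta2, higher by 1.11 with an SD of 0.71 in the miR-100 group, the T cell receptor partner gene Cd28 at -0.66, the skeletal muscle light chain gene Myl1 at -0.95, and Nppa, which is also in the hypertrophy list. Over all genes Myl1 passed without wild type replicate 1 (limma adjusted p = 0.0387) and Acta2 without miR-100 overexpressing replicate 4 (0.0442). Each passed in 1 of the 8 fits without an array, and their highest limma adjusted p there were 0.380 and 0.398. No smooth muscle marker (0) passed without wild type replicate 2, 3 or 4 or miR-100 overexpressing replicate 2. A further member passed adjusted over the list alone among skeletal muscle markers without wild type replicate 2 or miR-100 overexpressing replicate 2, and among atrial markers without miR-100 overexpressing replicate 2 or 3. In the same way 1 member passed among endothelial markers without miR-100 overexpressing replicate 4, fibroblast markers without replicate 1, adipocyte markers without replicate 3 or 4, and mesothelial markers without wild type replicate 1. The 3 measured Y-linked genes of the sex check had a median difference of 0.025.

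Camera at the preset correlation called 5 of 39 tested lists, 3 higher and 2 lower. With an estimated correlation it called 0, and fry, which tests whether a list's genes move on balance in a single direction, called 1, that of glycolysis. The mixed fry test called 14, namely ion channels, glycolysis, antioxidant defence, the clock, inflammation, hypertrophy, p53 and cell death, sarcomere, calcium handling, interferon, heat shock, hypoxia, and the atrial and the smooth muscle markers, and it does not compare a list with other genes.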

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

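The tests of an atypical array, of clock activator output, of atrial tissue, of Y chromosome content, of a sequence family and of gene order were chosen after the results were seen, and the counts over other splits of the arrays were chosen before.

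Each group of 4 arrays was searched for a value far from the other 3, over the array summaries and the genes named in the text, and 17 of 169 groups stood out, where chance gives about 5% of groups. Wild type replicate 2 held 3 of the array values. Its highest signal was 19.88 against 19.93 in the other wild type arrays, it had 0 rows at the ceiling against 7 to 8, and its mean correlation with its own group was 0.990 against 0.991 to 0.992. In miR-100 overexpressing replicate 4 the number of rows at the ceiling was 6 against 7.

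Single gene values that stood apart were those of Cd59a at 14.7 in miR-100 overexpressing replicate 4 (others 13.74 to 13.84), Ndnf at 9.6 in miR-100 overexpressing replicate 3 (others 9 to 9.1) and Hpcal1 at 8.78 in miR-100 overexpressing replicate 4 (others 9.38 to 9.42). In wild type replicate 3, Armc2 had 9.6 (others 10.26 to 10.36) and Per3 had 10.99 (others 11.26 to 11.31). Gpx1 had 11.36 in wild type replicate 1 (others 11.69 to 11.75) and 12.09 in miR-100 overexpressing replicate 4 (others 12.46 to 12.53). Sod3 had 9.26 in wild type replicate 2 (others 8.51 to 8.62), and Mx2 had 7.5 in miR-100 overexpressing replicate 3 (others 7.04 to 7.09). Near the ceiling, where values differ by hundredths, Tnnt2 had 19.85 in miR-100 overexpressing replicate 4 (others 19.79), Myh6 had 19.13 in wild type replicate 2 (others 19.18 to 19.19), and Atp2a2 had 19.86 in wild type replicate 2 and 19.84 in miR-100 overexpressing replicate 4 (others 19.85).

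Over the 35 splits of the 8 arrays into 4 and 4, the real split alone reached its 31 rows past the threshold, so 1 of 35 splits gave as many, and the highest other split gave 2. This argues against a chance split for this count. As 1 of 35 is the smallest share that the splits can give, chance is not excluded. For the 5 gene lists called by camera a chance split stays open, since 4 of 35 splits gave as many and the highest gave 6. For members past the threshold adjusted over each list alone, the real split gave 44 and the highest other 9. Again 1 of 35 splits gave as many, which argues against a chance split without excluding it.

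The clock genes moved in opposite directions between the groups. For the 12 members that passed adjusted over the list alone, the highest other split gave 6 and 1 of 35 gave as many. The clock list had the most such members of all lists in the real split, so the choice of list could favour it. In the other splits all lists together gave at most 9 such members, so no list there reached 12. This argues against a chance split without excluding it, as 1 of 35 is the smallest possible share. Wild type replicate 2 was not the whole source, since 10 members passed without it, and the lowest count was 8 without miR-100 overexpressing replicate 4. A plain fall in the output of the CLOCK and BMAL1 activator pair would lower its direct targets, and 9 list members were chosen as such targets. Of these, 7 lay lower by more than 2 standard errors. Nr1d1 lay higher by 0.80 (SE 0.19) and Nr1d2 differed by 0.03 (SE 0.14), so a fall of all 9 was not seen. Other list members were not counted, and the explanation stays open. Collection of the groups at different hours of the day was not tested, since collection times were not given in the sources used here, and it stays open beside an effect of miR-100 on the clock.

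The natriuretic peptide and stretch-responsive genes were higher in the miR-100 hearts. Atrial tissue in these samples would raise Myl7, Sln, Myl4 and Bmp10, transcripts known to be abundant in atria, yet their median difference was -0.14 against 1.04 for Nppa, which argues against it. Myl4 had 7.87 ± 0.13 in wild type and 7.61 ± 0.09 in miR-100 hearts (SD, n = 4 each), while Sln at 5.42, Myl7 at 4.23 and Bmp10 at 3.70 in wild type lay below the median row mean of 5.70, where a fall would be hard to see but a rise would not, if their probes respond. Without wild type replicate 2 Nppa still differed by 0.98, but its value on that array, 17.15, lay within the other wild type values. This check could therefore hardly fail. Without that array 4 members of the hypertrophy list passed adjusted over the list alone, against 5 with all arrays, and the camera adjusted p was 0.108. Dependence of the list's shift on that array thus stays open. A stress response of the ventricle to the transgene may account for the pattern, as a hypothesis found and examined on the same data. No test here decides it. Of the 26 measured members of the hypertrophy list 16 lay above 0 and 10 below, Myh7 among the latter.

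Of 350 rows without a gene name whose identifiers mark the X or Y chromosome, 2 passed the threshold with a fall and 4, of which 3 were distinct, lay below -2 at an adjusted p under 0.10 (limma), the third distinct one at 0.0627. TC0Y00000223.mm.2 went from 12.31 ± 1.07 to 8.32 ± 0.65 (SD, n = 4 each) and TC0X00001715.mm.2 differed by -2.77. The named Y chromosome genes had a median difference of 0.025, which argues against a lower share of Y transcripts. Of these, Kdm5d lay between 7.39 and 8.01 on all 8 arrays, which argues against mixed sex. A label swapped between male mice would leave the named Y chromosome genes unchanged, so a swapped label could not be tested this way. The 3 distinct rows below -2 had a mean correlation of 0.759 between their deviations from the group means, but 0.101 without wild type replicate 2, so a family of near-identical sequences read by several rows stays open, and the correlation rests on that array. Without it TC0Y00000223.mm.2 still differed by -3.46 and TC0X00001715.mm.2 by -2.31. A germline difference besides the transgene stays open too, because named genes past the threshold formed 3 pairs within 20 measured genes against 0.761 in random draws (permutation p = 0.0430) but 2 pairs without Cd59b (permutation p = 0.155).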

How the results depend on the processing

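The choice to count rows that share all values once was made after seeing the data, and gave 31 rows. The count of 31 rows past the threshold stayed between 28 and 43 with robust moderation, array weights, quantile normalization, median centring, filters on dim rows, named rows alone and a 1.5-fold minimum. It was 65 with an intensity trend and 65 at an adjusted p under 0.10. At an unadjusted p under 0.05 with at least 2-fold it was 84, a different rule that kept 26 of the 31 rows. Leaving out each array gave 11 to 27. The 5 lists called by camera became 0 with an estimated correlation and 1 with fry, and 4 to 5 with quantile normalization, an intensity trend or brighter rows; leaving out each array gave 1 to 5. The estimated correlation was 0.205 for interferon, 0.0865 for fatty acid oxidation, 0.0832 for hypertrophy and 0.0519 for the clock, against the preset 0.01. If these estimates hold, the preset camera p-values of those lists are too small. For glycolysis the estimate was -0.0352, so a correlation above the preset does not explain its loss. The cause of the other changes was not tested.

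With a replicate block the fit called 21 rows, of which 15 were among the 31, and 3 lists. Same-numbered arrays had correlations of deviations between -0.06 and 0.07, so the numbers do not pair the samples. The blocked differences of Nox4 and Cd36 were -0.23 and -0.06, where the sign-flip test cannot give an exact p below 0.125.

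Nox4 kept its direction without each array, from -0.30 to -0.10, and Cd36 from -0.11 to -0.0025. The Nox4 difference of -0.30 came without wild type replicate 3, in the 1 fit of the 8 without an array that passed the exact permutation test. There the lowest wild type value was 4.51 and the highest miR-100 value 4.50, and no correction was made for the 8 fits. Of the 21 named results past the threshold, 18 stayed past it with quantile normalization and 12 with the block, and 0 reversed. Of 57 other named genes 0 reversed with quantile normalization or the block. Past the threshold in addition came 1 of the 57 with quantile normalization and 2 with the block. Without single arrays, 96 of 168 values of the 21 results stayed past the threshold and 72 did not. For the 57 others 9 of 456 values came past it and 5 reversed, with Nr1d2 between -0.018 and 0.076 and Cpt1b between -0.039 and 0.052, both close to 0 throughout. All alternatives for the miR-100 seed sites were not run, since transcript sequences were not used here. Dim rows near the background, such as Nox4 and Phlda3 at percentiles 32.4 and 32.1 of all row means, are read with caution.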

Other observations

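The transferrin receptor gene Tfrc was singled out after its values were seen. It had 9.92 ± 0.90 in wild type and 12.03 ± 0.63 in miR-100 hearts (log2 signal, SD, n = 4 each), a difference of 2.10 (SE 0.39) that did not pass over all genes (limma adjusted p = 0.0627).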
